A study of Drosophila melanogaster with 2 samples.

How the data were processed

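Chromatin immunoprecipitation sequencing (ChIP-seq) was carried out with an antibody against GFP on sonicated chromatin from whole Drosophila melanogaster prepupae of both sexes, per the labels. The labels also give an age of 48 days, which disagrees with that stage and was not used. The animals carried a transgene that encodes Dachshund (gene dac) with enhanced GFP fused to its C-terminus. The series holds 1 group of 2 biological replicates, which the labels number 1 and 3. No second stage, genotype or mock sample was analysed here, so every comparison is between replicates, between parts of the genome or between gene groups within the group. A control library that the labels list was not analysed here.

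The authors deposited peak lists, not reads or counts. For each replicate and for both replicates pooled there is a relaxed list of exactly 30000 peaks, which the authors named as the input to the irreproducible discovery rate (IDR) procedure, a method that keeps peaks ranked alike in replicates. A further list, which the authors named optimal, holds the peaks that passed the IDR threshold, and it draws on both replicates. Each list was given on 2 genome builds, dm6 and dm3. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. The signal of each peak is the authors' own value, deposited without a stated scale. The scale differed between lists, so signal was compared between lists only by rank. The q-value of each peak was deposited by the authors as −log10 q and is capped in each list. All 4137 peaks of the IDR list on dm6 sit at that cap, so q was used only to count peaks of the relaxed lists at 0.05 or less. The read depth of the replicates is unknown, and intervals below cover only the number of peaks counted.

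The IDR list on dm6 was the main list. All of its peaks lay inside the chromosome arm lengths of the reference assembly (Release 6), and 4132 of its 4137 peaks were among the 4137 highest of the pooled relaxed list. In the relaxed lists of the replicates, 115 of its peaks overlapped no peak of replicate 1 and 26 none of replicate 3. Not every IDR peak was therefore seen in both replicates. Coordinates are 1-based on dm6. Genes came from Ensembl release 115, with 13945 protein-coding genes. Transcription start sites (TSSs) and annotation classes used protein-coding and non-coding RNA genes on arms 2L, 2R, 3L, 3R, 4 and X. Each summit was given a single class in the order promoter (within 500 bp of a TSS), coding sequence (CDS), UTR, other exon, intron and intergenic. The class came from any annotated gene at the position, not only from the nearest gene. A gene was called bound when its TSS was the nearest protein-coding TSS of at least 1 summit. With dm3 neither annotation nor arm lengths were used, so the dm3 lists served for counts and for the agreement of replicates.

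The density on X was set against autosomes with Fisher's exact test (two-sided) on peaks against arm length in kilobases. The agreement of replicates was the share of the 4137 highest-signal peaks of one replicate that overlapped by at least 1 bp a peak among the 4137 highest of the other, beside 100 shuffles along the arms. Classes and distances between summits were also set against 100 shuffles within arms, for which 0.0198 is the smallest two-sided p possible. Promoter and distal signal were compared by the difference of median log2 signal with a permutation test of 100000 resamples (two-sided).

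For 20 gene lists, the number of bound members was set against 10000 random lists of protein-coding genes matched in 20 bins of territory, the length of the gene body plus the distance from its outer TSSs to the midpoints with the TSSs of the neighbouring genes. The two-sided p was adjusted over the 20 lists (Benjamini-Hochberg). The smallest raw p was 0.0002. Of the symbols in the lists, 5 were retired ones that were mapped to current names, among them Dl to Delta and tal to tal-1A. For 20 sequence motifs, the share of summits with a match on either strand within 100 bp was set against 5 random windows per peak of the same class and GC content (in bins of 2%), kept at least 1000 bp from any peak. Fisher's exact test (two-sided) was adjusted over the 20 motifs. Shares of peaks carry 95% Wilson intervals.

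Lists, motifs, tests and most alternatives were fixed before the data were examined. So was the rule for named genes. It takes dac, the nearest genes of the 15 highest-signal IDR peaks seen in both replicate lists, and the 5 genes with most IDR peaks. From each list it takes up to 4 bound members with the highest signal, and from the retinal determination list all members. A further 6 gene lists, all 6-mers and 8-mers, counts in bins around the summits and 5 alternatives were chosen after the data had been seen. Their results are in the closing section, apart from the bins for GAGAGAG, which are given beside that motif. Alternatives covered the build, the overlap rule, the windows, the assignment of peaks to genes, the matching, a stricter list (IDR peaks above the median signal) and each replicate alone. Leaving out a replicate meant taking the 4137 highest-signal peaks of the other one.

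The tests were tried on simulated data. With lists of 40 genes drawn towards long territories and no true difference, over 13945 genes, the matched test called 4.00% of lists, and Fisher's exact test without matching called 57.0%. With the chance of being bound doubled, the matched test called 99.5%. These calls used unadjusted p below 0.05. Without a true difference, the simulated chance of being bound depended only on territory, the variable that was matched. The rate of false calls therefore does not cover other differences between listed and matched genes. Most of the fixed lists had fewer than 40 members and were judged on adjusted p, so their power is not shown by this simulation. The motif test on a single draw of 4137 random windows called 0 of the 20 motifs, and it recovered 100% of them when planted. Each motif was planted in a larger share of windows than any difference found between IDR summits and matched windows. Weaker enrichment was not simulated, so a motif that did not pass is not shown to be absent. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.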

Results

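ChIP-seq with an antibody against GFP was used to map sites of GFP-tagged Dachshund in whole Drosophila animals that the labels call prepupae. No mock or untagged sample was analysed here, so peaks from non-specific recovery cannot be told apart from sites of the tagged protein. Dachshund is a nuclear protein of the retinal determination network, and it is also needed in legs and in the mushroom bodies of the brain. The authors' IDR list held 4137 peaks from 2 biological replicates, with a median width of 410 bp. Their signal ran from 109.8 to 2090.3 around a median of 172. The nearest TSS belonged to 2406 of 13945 protein-coding genes. At q of 0.05 or less the relaxed list of replicate 1 held 5282 peaks and that of replicate 3 held 13828. Read depth is unknown.

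The strongest peak lay at the promoter of Ugalt (FBgn0024994), a UDP-galactose transporter gene, on X from 2703707 to 2704079, with a signal of 2090.3 and its summit 47 bp from the TSS. It ranked 1 in the pooled list and 1 in each replicate. The next was at the promoter of CG14100 (3L, 19590436 to 19590802), with a signal of 1868 and rank 2 in both replicates. An intron peak of cbt, which encodes a zinc-finger transcription factor, followed at 1616 (2L, 480894 to 481295), and a promoter peak of PNPase, a mitochondrial RNA-degrading enzyme, at 1603 (3R, 31404490 to 31404835). The HMG-box gene HmgZ had an intron peak of 1523 (2R, 21703129 to 21703695). Trl, which encodes GAGA factor, had an intron peak of 1483 (3L, 14759307 to 14759724). RYBP, a Polycomb partner, had an intergenic peak of 1468, with its summit 7643 bp from the TSS (2R, 22678127 to 22678664). Chro, an interband chromodomain protein gene, had a promoter peak of 1347 (3L, 22878714 to 22879083).

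The remaining genes among the 15 strongest sites were CG4004, CG32772, CG31145, CG11050, larp, CG13323 and Tcs5, with signals from 1552 at CG4004 to 1293 at Tcs5. The peak assigned to CG4004 was at a non-coding RNA promoter, 5080 bp from the TSS of CG4004. Of the 15 sites, 8 were at promoters, 5 in introns and 2 in intergenic sequence. All 15 ranked within the top 32 of replicate 1 and the top 15 of replicate 3. These ranks describe the authors' signal and carry no test.

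At the tagged gene itself, dac (FBgn0005677), 3 IDR peaks lay within 1 kb of its TSS on 2L. The promoter peak ran from 16485625 to 16486034 with a signal of 196, and its summit was 168 bp from the TSS. The other 2 were intergenic, from 16486407 to 16486593 with a signal of 217 and from 16486613 to 16487022 with a signal of 115.1. They ranked 1697, 1471 and 3866 in the pooled list, in the order given. Both intergenic peaks overlapped the same peak of each replicate, which ranked 1488 in replicate 1 and 1471 in replicate 3. The strongest 4137 peaks of replicate 1 alone held 5 near dac, and those of replicate 3 held 2.

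The replicates shared most of their strongest sites. Of the 4137 highest-signal peaks of replicate 1, 2936 overlapped one of replicate 3 (71.0%, 95% Wilson interval 69.6 to 72.3), and in the other direction 2866 did (69.3%). Shuffled lists shared 2.18% on average and 2.83% at most. Of the IDR peaks, 4022 overlapped a peak in the relaxed list of replicate 1 and 4111 one in that of replicate 3. Across the 3996 IDR peaks found in both lists, the Spearman correlation of signal was 0.663. Peaks are not independent replicates, so no p was attached.

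Chromosome X carried the highest density of peaks and chromosome 4 the lowest. There were 885 IDR peaks on X, or 37.6 per Mb, against 29.5 per Mb over the autosomes, a ratio of 1.28 (Fisher's exact test, two-sided, p = 1.8e-10). The weaker peaks of the pooled list outside the IDR list had a ratio of 1.197 (5082 and 19896 peaks), and whether the ratios differ was not tested. The large autosomal arms were alike, with 30.7 per Mb on 2L, 28.6 on 2R, 30.3 on 3L and 29.6 on 3R. Chromosome 4 held 6 peaks, or 4.45 per Mb. Away from promoters, more than 500 bp from any TSS, the ratio of X to autosomes was 1.34 (571 and 2000 peaks). Neighbouring peaks were not independent, as 203 adjacent pairs overlapped, so the p is smaller than independent sites would give.

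The IDR peaks were concentrated at promoters and were nearly absent from coding sequence. Promoters held 1566 summits (37.9%, 36.4 to 39.3), against 13.0% of random positions, a 2.90-fold excess. Introns held 1849 (44.7%, 43.2 to 46.2), against 39.8% (38.1 to 41.8 over the shuffles), but in the list of replicate 3 alone the share of 41.5% was inside that range. Intergenic sequence held 620 (14.99%, 13.9 to 16.1), against 27.3%, UTRs 54 (1.31%) against 5.14%, and coding sequence 6 (0.145%, 0.0665 to 0.316) against 13.9%. Other exons held 42 (1.02%) against 0.764%, inside the range of the shuffles (0.459 to 1.09). The promoter excess had p = 0.0198 (permutation of positions), the smallest that 100 shuffles can give. Against the 24978 weaker peaks of the pooled list outside the IDR list, of which 20.6% were at promoters, the excess was 1.83-fold (Fisher's exact test, p = 4.8e-119). Of those weaker peaks 50.6% were in introns, a higher share than in the IDR list, 22.6% in intergenic sequence and 2.30% in coding sequence.

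**Figure D1:**
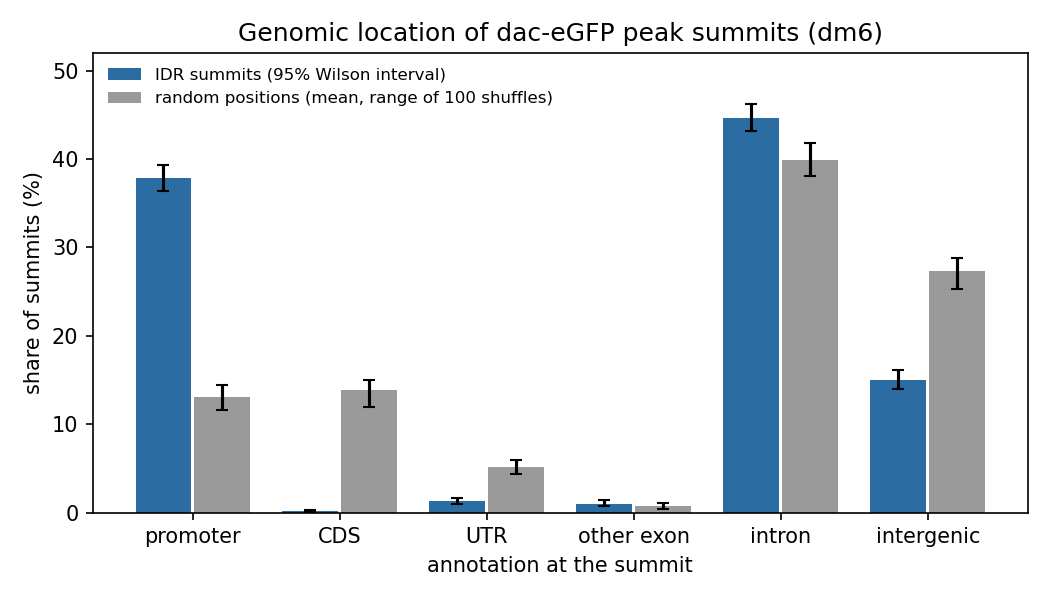
Share of IDR summits (blue, with 95% Wilson intervals) and of random positions (grey, mean and range of 100 shuffles) in each annotation class, in percent. Promoters take 37.9% of summits against 13.0% of random positions, and coding sequence takes 0.145% against 13.9%.

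Most promoter summits lay just upstream of the start site. Of 1455 summits within 500 bp of a protein-coding TSS, 1167 were upstream (80.2%, 78.1 to 82.2). Their median position was −125 bp. Promoter peaks had a slightly higher signal than the 2571 distal peaks, with medians of 187 and 167. The difference of 0.17 on the log2 scale had p = 1e-05 (permutation test, two-sided), the smallest the test allows. In the list of replicate 3 alone the difference was 0.09 (permutation test, p = 0.0025).

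Genes of the morphogen pathways that pattern imaginal discs were bound more often than genes with territories of the same length. Of 22 members, 19 had an IDR peak, against 8.82 in matched lists (5 to 13, the central 95%). The strongest was an intron peak of dpp, the BMP-type ligand, with a signal of 737 (2L, 2433485 to 2433801, pooled rank 83). Intron peaks of 509 at brk, the repressor of Dpp targets, and of 508 at sty, an antagonist of receptor tyrosine kinase signalling, followed. There were 6 peaks near brk and 5 near sty, where the list of replicate 1 alone had 3 and the IDR peaks above the median signal were 2. The EGF receptor ligand gene vn had 1 intron peak of 431. The members without a peak were en, hh and ci, named after their values were seen. By permutation over matched lists the adjusted p (Benjamini-Hochberg, two-sided) was 0.002, the smallest possible here, and both replicates alone gave 19 bound members. By the same permutation test, the call was lost when a summit had to lie in the gene body or within 5000 bp (16 against 10.6, adjusted p = 0.168) or within 1000 bp of a TSS (7 against 4.86, adjusted p = 0.859).

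Cytosolic ribosomal protein genes formed the other list above its matched genes. Of 88 members, 39 were bound, against 9.13 expected (4 to 15, permutation test, adjusted p = 0.002, the smallest possible). The peaks sat at the start sites, with 38 of 39 within 200 bp of the TSS at a median distance of 27 bp. The strongest were at the promoters of RpL7 (signal 454, 2L, 10200907 to 10201161), RpS27 (438, 3R, 25247388 to 25247654) and RpL34b (353, 3R, 9401180 to 9401402). The exception was RpL37A, whose peak of 318 lay in an intron 9644 bp from its TSS (2L, 5080439 to 5080848). The median signal of the 39 peaks was 191, against 172 over the IDR list. The list of replicate 1 alone gave 25 bound genes and that of replicate 3 gave 42, both with adjusted p = 0.002 by permutation. Of the 39 peaks, 7 had no overlapping peak in replicate 1 and 0 lacked a peak in replicate 3. Over all 4137 IDR peaks these numbers were 115 and 26. Proteasome genes were not above their matched genes, with 4 of 48 against 5.06 (Rpn3, Rpn9, Prosbeta2 and Prosbeta5R1, permutation test, adjusted p = 1.00). That list also held 16 paralogues whose names have T or R after the subunit number, Prosbeta5R1 among them, and of the other 32 members 3 were bound.

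Genes of the response to the steroid ecdysone had 14 of 24 members bound against 7.96 expected (4 to 12). This did not pass the adjusted threshold (permutation test, p = 0.0162, adjusted p = 0.108). The strongest peaks were at the promoter of the ABC transporter gene E23 (signal 806, 2L, 3354887 to 3355269) and in introns of the nuclear receptor genes Hr4 (679, X, 1951768 to 1952066) and Eip75B (635, 3L, 18009021 to 18009337). An intron of the ETS factor gene Eip74EF followed with 487 (3L, 17611449 to 17611683). Hr4 had 12 peaks and Eip75B had 10. The list passed when a summit in the gene body or within 5000 bp was counted (20 against 10.7, permutation test, adjusted p = 0.0060). It also passed in the list of replicate 3 alone (15 bound, permutation test, adjusted p = 0.028), and not in that of replicate 1 (13 bound, adjusted p = 0.297). Within 1000 bp of a TSS it had 7 against 4.76 (permutation test, adjusted p = 0.859).

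Of the other genes of the retinal determination network, 2 of 12 were bound, against 4.48 expected (1 to 8, permutation test, adjusted p = 0.655). They were so, a homeobox gene, with a promoter peak of 186 (2R, 7418904 to 7419313), and tsh, a zinc-finger gene, with an intergenic peak of 130 whose summit lay 17962 bp from the TSS (2L, 21846350 to 21846759). No IDR summit had eya, ey, toy, Optix, eyg, toe, tio, dan, danr or nmo as its nearest gene. The list of replicate 1 alone gave 3 bound members against 4.62 expected, and that of replicate 3 gave 3 against 4.34. In the relaxed pooled list nmo was nearest to 22 peaks, toe to 6, ey and dan to 5 each, eya, Optix and tio to 4 each, eyg to 2, danr to 1 and toy to 0.

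The lists for other organs in which Dachshund acts lay inside the range of their matched genes. Leg and antenna patterning had 7 of 16 members bound against 6.27 (permutation test, adjusted p = 1.00), led by bab2 (signal 266), hth (206), bab1 (174) and Sp1 (143). The Notch and leg joint list had 5 of 13 against 4.57 (permutation test, adjusted p = 1.00), led by bowl (429), fng (380), tal-1A (221) and dysf (127). The mushroom body list had 10 of 16 against 6.36 (permutation test, adjusted p = 0.343), led by the cAMP phosphodiesterase gene dnc (659), Syp (295), Fas2 (174) and ab (160). Early photoreceptor genes had 3 of 15 against 4.75 (pnt with 482, aop with 294 and oc with 178, permutation test, adjusted p = 1.00). Phototransduction genes had 3 of 15 against 3.64 (norpA with 552, Rh5 with 285 and ninaC with 132, permutation test, adjusted p = 1.00). Hox genes had 3 of 8 against 3.46 (Antp with 198, lab with 111 and Abd-B with 110.4, permutation test, adjusted p = 1.00).

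Markers of other tissues in the whole animal did not pass the threshold in either direction. Cuticle and chitin genes had 0 of 23 bound against 3.07 expected (0 to 6, permutation test, adjusted p = 0.243). With summits in the gene body or within 5000 bp they had 2 against 8.58, which passed (permutation test, adjusted p = 0.0333). The list of replicate 1 alone gave 2 against 2.81, and that of replicate 3 gave 1 against 3.31. Neuron genes had 1 of 12, elav with a promoter peak of 667, against 4.58 (2 to 8, permutation test, p = 0.0498, adjusted p = 0.243). With summits in the gene body or within 5000 bp they had 5 against 5.57. The lists of replicates 1 and 3 alone gave 2 and 1 bound neuron genes. Muscle genes had 4 of 16 against 4.77 (sls with 270, Mef2 with 195, Act87E with 147 and Tm1 with 116). Glia had 1 of 8 against 1.62 (moody with 656), fat body 2 of 9 against 2.02 (bmm with 232 and Apoltp with 158), and salivary gland 2 of 14 against 1.71 (CrebA with 241 and fkh with 133). Hemocytes had 2 of 11 against 2.498 (crq with 391 and srp with 192), midgut 2 of 10 against 1.67 (Myo61F with 420 and esg with 137), and trachea 3 of 7 against 2.64 (rib with 189, knrl with 145 and vvl with 129). The adjusted p of these last 6 lists and of muscle was 1.00.

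**Figure D2:**
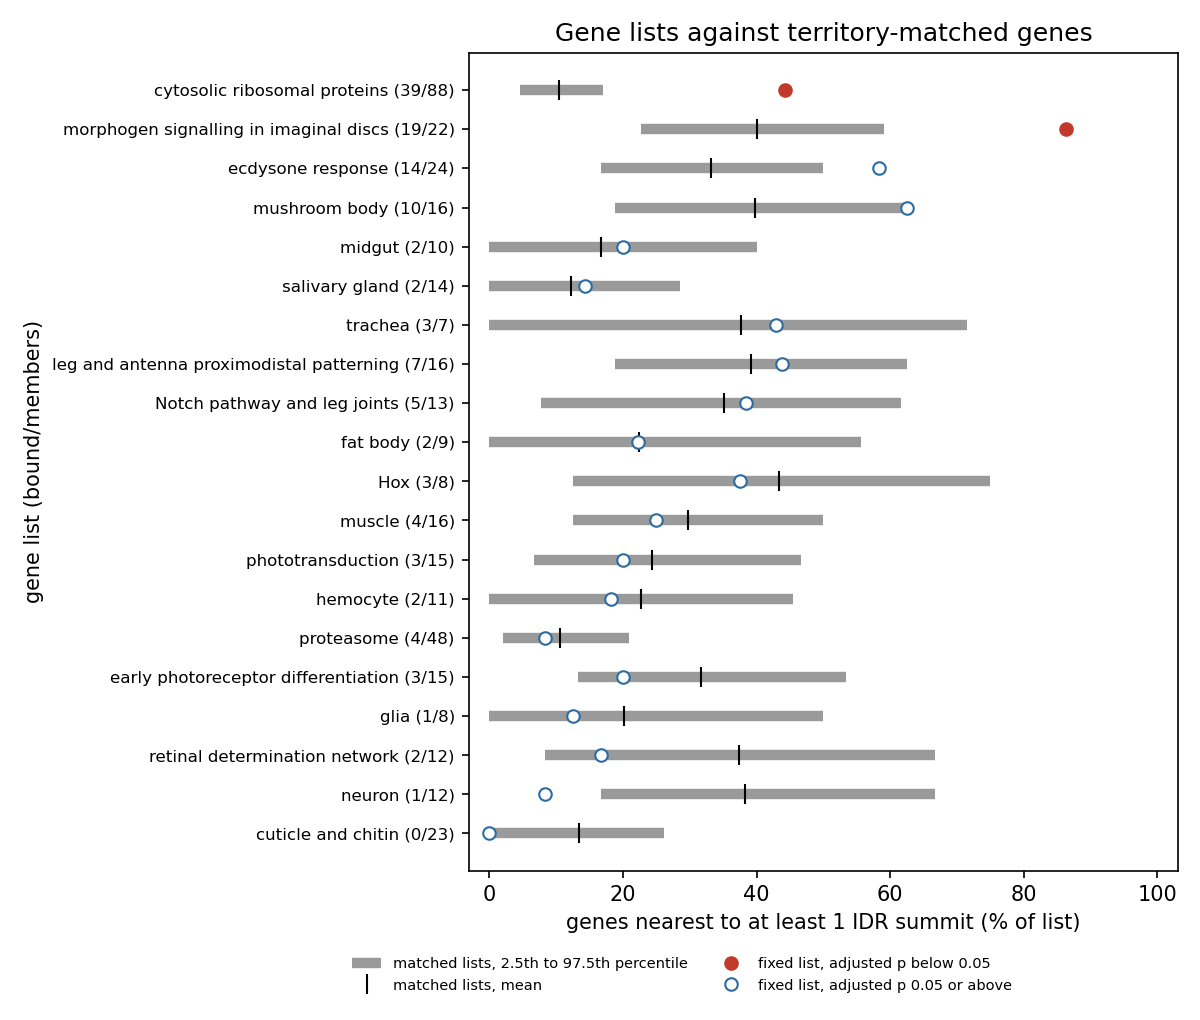
Share of each fixed gene list, in percent of its members, that was nearest to at least 1 IDR summit (circles), beside 10000 territory-matched lists (grey bar, the central 95%, black tick, mean). Filled red circles mark the lists that passed, cytosolic ribosomal proteins (39 of 88) and morphogen signalling (19 of 22), and open blue circles mark the other lists.

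Among the 20 fixed motifs, GAGA repeats had the largest ratio over matched windows. GAGAGAG, the site of GAGA factor, was found within 100 bp of 228 summits (5.51%, 4.86 to 6.25), against 2.10% of matched windows, a ratio of 2.63 (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted p = 3.3e-28). The site of the insulator protein Su(Hw) was at 38 summits (0.919% against 0.450%, ratio 2.04, Fisher's exact test, adjusted p = 0.0015) and that of the core promoter factor M1BP at 62 (1.499% against 0.740%, ratio 2.03, adjusted p = 5.3e-05). The proneural E-box CAGCTG was at 324 (7.83% against 5.91%, ratio 1.33, Fisher's exact test, adjusted p = 5.3e-05), and the Sine oculis family core TGATAC at 262 (6.33% against 5.45%, ratio 1.16, adjusted p = 0.0477). Against windows 1000 bp to either side of the same summits the ratio of GAGAGAG was 1.28 (Fisher's exact test, adjusted p = 0.0060), and the E-box was below its flanks (0.891, adjusted p = 0.116). Against those flanks Su(Hw) (2.53), DREF (2.28) and M1BP (2.21) had higher ratios than GAGAGAG. So did the Sine oculis family core (1.46, Fisher's exact test, adjusted p = 1.5e-05) and the paired-class homeodomain palindrome (1.45, adjusted p = 0.0086). Within 50 bp the ratio of GAGAGAG was 1.64, below CTCF (2.73), M1BP (2.69) and Su(Hw) (2.17). In bins of 40 bp, counted after this result was seen, GAGAGAG was rarest next to the summit (0.943 and 1.43 per 100 peaks) and most frequent 120 to 160 bp from it, on the side of higher coordinates (4.96). Among the motifs above their background, only GAGAGAG also passed in the IDR peaks above the median signal (ratio 2.49).

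Other motifs were less frequent at summits than in matched windows. These were AGGTCA, the core site of nuclear receptors (3.63% against 5.16%, ratio 0.702, Fisher's exact test, adjusted p = 8.4e-05), the Scalloped site CATTCC (0.807, adjusted p = 0.0016), the ETS site CCGGAA (0.805, adjusted p = 0.0362), the Homothorax core TGACAG (0.848, adjusted p = 0.0362), the Zelda site CAGGTA (0.823, adjusted p = 0.0477) and the Exd-Hox site TGATNNAT (0.910, adjusted p = 0.0477). Over the 5 other settings fixed beforehand, GAGAGAG and CATTCC passed in the same direction in 5, AGGTCA and Su(Hw) in 4, the E-box, M1BP and the Homothorax core in 3, ETS and the Sine oculis and Exd-Hox motifs in 2, and Zelda in 1. In the list of replicate 1 alone, M1BP (ratio 1.46, Fisher's exact test, adjusted p = 0.0695), the Sine oculis core (1.14, adjusted p = 0.104), Exd-Hox (0.933, adjusted p = 0.139) and Zelda (0.878, adjusted p = 0.170) did not pass, and in that of replicate 3 ETS did not (0.852, adjusted p = 0.0836). The direction turned for Exd-Hox against flanks (1.10) and for ETS within 50 bp (1.03). The other 9 motifs did not pass in the IDR list.

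**Figure D3:**
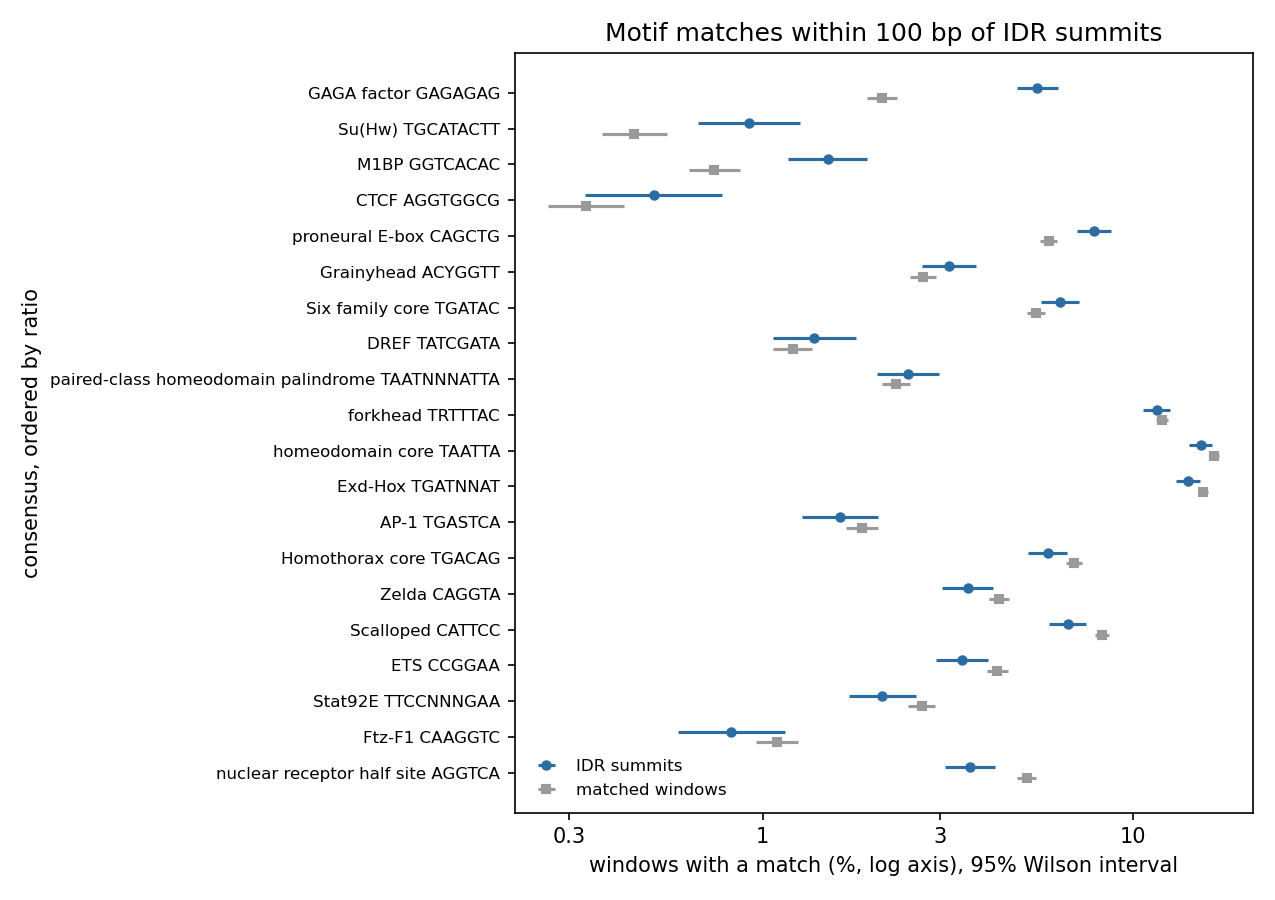
Share of IDR summits (blue) and of matched windows (grey) with a match to each consensus within 100 bp, in percent on a log axis, with 95% Wilson intervals. GAGAGAG lies at 5.51% of summits against 2.10% of matched windows, and AGGTCA at 3.63% against 5.16%.

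Peaks lay in groups, and several long genes carried many of them. In the IDR list tara, a cell cycle and chromatin regulator, had 16 peaks (3R, 16225651 to 16260329) and the Tousled-like kinase gene Tlk with 15 (X, 3720007 to 3789770). Hr4, hng3 and the Myc antagonist gene Mnt had 12 each. Their order changed between lists: replicate 3 alone gave 14 for Tlk and 12 for tara, replicate 1 alone 11 and 18, and above the median signal Mnt had 10, tara 8, Tlk and Hr4 7 each and hng3 5. The sequence nearest to the TSSs of these genes was 38.005 kb for tara, 65.2 kb for Tlk, 59.7 kb for Hr4, 46.1 kb for hng3 and 32.8 kb for Mnt, at or above the 95th percentile of all genes. The median distance between neighbouring summits was 9.86 kb, against 22.0 kb for random positions (21.2 to 23.1), a ratio of 0.447 (permutation of positions, p = 0.0198, the smallest that 100 shuffles can give). Against sites drawn from the relaxed pooled list the ratio was 0.717 (permutation, p = 0.0198). There were 115 genes with 5 or more peaks, against 61.7 for random positions and 107 for relaxed sites (132 at most).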

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

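These counts were chosen after the lists had been seen, and no test was run on them. They are noted because peaks were listed on sequence, or at ranks, that the comparisons above do not use, and no control sample analysed here sets a level for them. In the relaxed lists on dm3, replicate 1 had 150 peaks on heterochromatic or unplaced sequence and replicate 3 had 10. In the relaxed lists on dm6, replicate 1 had 291 peaks on chromosome 4 outside its 4137 strongest and replicate 3 had 25. On chromosome 4 the numbers at q of 0.05 or less were 16 in replicate 1 and 21 in replicate 3, and 9 peaks of each replicate were among its 4137 strongest. Of the 300 chromosome 4 peaks of replicate 1, 26 overlapped a peak of replicate 3, and of the 34 of replicate 3, 28 overlapped one of replicate 1. No explanation was tested for these differences between the replicates.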

How the results depend on the processing

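Of the alternatives below, matching on the sequence nearest to the TSS, matching on relaxed peaks, the looser list, merged peaks and windows without repeats were chosen after the data had been seen. The number of IDR peaks was 4137 on dm6 and 4165 on dm3. The X ratio (1.16 to 1.36), the promoter excess (1.83 to 3.94), the promoter signal (0.09 to 0.21 on the log2 scale) and clustering (0.430 to 0.717) kept their direction and passed in every setting run. The overlap of replicates was 51.8% with 50% of each peak required, 62.3% for summits within 100 bp, 75.6% for the 2068 highest peaks and 64.3% for the 8274 highest. The rank correlation of signal between replicates was 0.685 in the stricter list. The promoter share was 23.3% with a 200 bp window, 49.2% with 1000 bp, 41.7% in the stricter list, and 34.4% to 42.0% with either replicate left out. Instead of 2 gene lists, 1 passed within 1000 bp of a TSS, 5 without matching and 4 in the looser list (pooled peaks at q of 0.05 or less, adding the ecdysone and the Notch lists). Across the settings, the adjusted p ranged from 5.4e-11 to 0.859 for the morphogen list, from 2.8e-08 to 0.0040 for ribosomal protein genes and from 4.6e-05 to 0.859 for the ecdysone list (permutation test, or Fisher's exact test without matching). Matched on relaxed peaks, the morphogen list had 19 against 12.2 (permutation test, adjusted p = 0.044), close to the threshold. With the same matching, the ecdysone list had 14 against 11.2 (permutation test, adjusted p = 0.827). Over 20 lists, 121 results stayed on their side of the threshold in the same direction, 8 newly passed and 2, both of the morphogen list, no longer did. For lists that passed in neither setting, the direction against matched genes turned in 49 results, given as bound members against the number expected. With the gene body and 5000 bp, these were leg 7 against 7.56, muscle 7 against 6.79, glia 4 against 2.91, fat body 4 against 3.45, salivary gland 4 against 4.99, midgut 1 against 3.73 and trachea 2 against 3.23. Within 1000 bp of a TSS, these were leg 2 against 3.34, Notch 2 against 2.56, muscle 3 against 2.98, fat body 2 against 1.47, midgut 1 against 1.55 and trachea 1 against 1.51. Without matching, these were early photoreceptor 3 against 2.59, phototransduction 3 against 2.59, Hox 3 against 1.38, muscle 4 against 2.76, fat body 2 against 1.55, salivary gland 2 against 2.42 and hemocyte 2 against 1.90. In the stricter list, these were leg 3 against 4.13, mushroom body 3 against 4.23, glia 1 against 0.988, salivary gland 1 against 1.06, hemocyte 2 against 1.53, midgut 1 against 1.00 and trachea 1 against 1.73. Without replicate 1, these were early photoreceptor 5 against 4.67, Hox 4 against 3.41, glia 2 against 1.65 and fat body 3 against 2.03. Without replicate 3, these were leg 5 against 6.46, fat body 2 against 1.963 and salivary gland 1 against 1.59. In the looser list, these were retinal determination 7 against 6.87, leg 9 against 9.21, early photoreceptor 9 against 7.27, Hox 5 against 4.84, salivary gland 2 against 2.84 and midgut 2 against 2.74. Matched on sequence nearest to the TSS, this was fat body 2 against 1.82. Matched on relaxed peaks, these were leg 7 against 7.38, Notch 5 against 6.83, phototransduction 3 against 2.61, muscle 4 against 2.96, fat body 2 against 1.43, salivary gland 2 against 2.21, hemocyte 2 against 1.63 and trachea 3 against 3.24. Instead of 5 motifs, 8 passed against flanks 1000 bp away and 1 in the stricter list. Against flanks the direction turned for the homeodomain core (1.19), Exd-Hox (1.10), the E-box (0.891), forkhead (1.204) and Grainyhead (0.957). Of these, the homeodomain core (Fisher's exact test, adjusted p = 0.00079) and forkhead (adjusted p = 0.0020) passed against flanks, and the others did not. With 50 bp windows the direction turned for ETS (1.03), the paired palindrome (0.916), Grainyhead (0.836) and forkhead (1.06). In the stricter list it turned for Grainyhead (0.868), forkhead (1.04), DREF (0.816) and AP-1 (1.09), and with either replicate left out AP-1 ranged over 0.908 to 1.08, turning without replicate 1, and DREF over 0.870 to 1.63, turning without replicate 3. Of the other motif results, 76 kept their side of the threshold and direction, 8 newly passed and 21 no longer did. Of the peak counts of named genes, 197 stayed within 1.5 times and 61 did not. The cause was not tested. Annotation on dm3 was not run, and no agreement of replicates can be had with one left out. No paired analysis was possible because there is only 1 group. Unknown read depth limits how far weaker sites can be compared.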

Other observations

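The lists of further gene groups, the 6-mer and 8-mer counts, the comparisons with proteasome and mitochondrial ribosomal protein genes and the share of matches within 100 bp were chosen only after the results had been seen. Genes of the Polycomb and trithorax groups, which keep developmental genes off or on, were bound more often than territory-matched genes, with 17 of 33 against 8.20 (4 to 13, permutation test, adjusted p = 0.0048 over 6 such lists). The strongest peaks after those of Trl and RYBP were a peak assigned to osa (signal 1185, 3R, 17704249 to 17704619) and a promoter peak of ph-p (1102, X, 2136931 to 2137623). Those of Psc (661) and trx (473) followed. The peak assigned to Psc was at a non-coding RNA promoter, 4226 bp from the TSS of Psc. The osa peak lay in an exon outside coding sequence and UTRs, 13925 bp from the nearest TSS of osa. Which gene that exon belongs to was not determined. Genes of the Hippo growth control pathway had 9 of 13 members bound against 3.29 (1 to 6, permutation test, adjusted p = 0.0048), led by the cadherin gene ds (731, 2L, 715404 to 715736), ex (553), kibra (538) and ft (371). These genes were named after their values were seen. Both lists were picked because some of their members stood among the strong peaks, so their p is not independent evidence. Both replicates alone gave similar counts, 16 and 18 for the Polycomb and trithorax list and 8 and 9 for the Hippo list.

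The other lists of this kind did not pass. Heat shock protein genes had 5 of 14 against 1.90 (permutation test, adjusted p = 0.112), with a promoter peak of 1247 at Hsp27 (3L, 9383705 to 9384082) that ranked 16. Cell death genes had 3 of 9 against 2.19, hid, Diap1 and rpr (permutation test, adjusted p = 1.00). Mitochondrial ribosomal protein genes had 6 of 73 against 6.01 (permutation test, adjusted p = 1.00), although mRpL23 (961) and mRpL41 (941) ranked 39 and 42. Translation factor genes had 9 of 54 against 8.56 (permutation test, adjusted p = 1.00), with eIF6 (1106) and eEF1gamma (1005) at ranks 24 and 37. The peak assigned to eEF1gamma was at a non-coding RNA promoter, 5717 bp from the TSS of eEF1gamma.

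The peaks at cytosolic ribosomal protein genes, 39 of 88 genes, could come from their high transcription, from housekeeping promoters in general, or from a single replicate. Proteasome and mitochondrial ribosomal protein genes were bound in 8.26% of cases (10 of 121) against 44.3% (Fisher's exact test, p = 1.6e-09). Without 16 proteasome paralogues whose names have T or R after the subunit number the share was 8.57% (9 of 105, Fisher's exact test, p = 1.1e-08). Both lists had been seen at their matched level before this comparison was chosen, so its outcome was not open. The pattern was not shared by these families, and housekeeping promoters in general stay undecided. The replicate with the lower count still had 25 bound genes against 8.45 in matched lists (4 to 14), which argues against a single replicate as the source of the whole pattern, although 7 of the 39 peaks overlapped no peak of replicate 1 and rest on replicate 3. Of 290 tRNA genes, 3.45% lay within 500 bp of a summit, against 2.96% for shuffled summits (0.690 to 5.52), so recovery of highly transcribed loci stays open, since transcription was not measured here. No biological explanation was tested, as the design has 1 group.

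The low count at retinal determination genes, 2 of 12, was inside the range of matched genes, and a candidate explanation is that the IDR threshold or the assignment to the nearest TSS hid sites. At q of 0.05 or less in the pooled list 7 members were bound, against 6.87 in matched lists (3 to 10), so the looser list brought the members to the level of other genes and not above it. With a summit in the gene body or within 5000 bp the count was 2 against 5.28 (2 to 9), and the members were so and nmo, with tsh lost and nmo gained. With 12 genes neither explanation can be excluded, and sites farther than 5000 bp from a gene were not covered by the latter test.

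Of 2080 6-mers, 359 were enriched and 453 depleted (adjusted p of 0.05 or less), so that passing alone says little. ACAGTG had the lowest p, within 100 bp of 781 summits (18.9%) against 7.34% of matched windows, a ratio of 2.57, and among 8-mers CACTGTGC had a ratio of 8.55 (5.12% against 0.599%). In the 3805 windows without CA or GA repeat runs the ratio was 2.60, so the excess was not confined to windows with such runs. Only 332 windows held them, too few for their removal to reach the bound set beforehand, so that bound decides nothing on repeats. In the 4686 weaker peaks outside the IDR list with q of 0.05 or less, the ratio was 1.98 (Fisher's exact test, p = 5.6e-54). This argues against selection on the same peaks, and peaks above that q were not covered. Of 2848 matches within 500 bp, 13.0% were within 50 bp of the summit, between the bounds set beforehand. Within 100 bp were 32.6% (30.9 to 34.4), against 20.2% for an even spread. ACAGTG had been picked by its share within that same 100 bp, so the share among matches does not decide against a property of the wider regions. In windows 1000 bp to either side of the summits, not used to pick it, ACAGTG was in 8.40%. That is near the 7.34% of matched windows and below the 18.9% at summits. These values argue against a property shared by sequence 1000 bp away, and nearer sequence was not compared in this way. The sequence may mark a recurrent element of these sites (ratio 2.60 without repeats), a hypothesis found and tested in the same libraries, and no factor was tied to it here.

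ACAGTG matches were most frequent 40 to 120 bp from the summit, at up to 5.58 per 100 peaks in 40 bp, with 3.07 and 3.41 in the bins next to it. ACAGTG was as frequent at promoters (18.6%) as at distal summits (19.0%, Fisher's exact test, p = 0.775), and more frequent among the stronger IDR peaks (21.3%) than among the weaker ones (16.5%, p = 8.3e-05). GAGAGAG was more frequent at promoters (7.28%) than at distal summits (4.43%, Fisher's exact test, p = 0.00014), and it was in 0 of the 39 peaks at ribosomal protein genes, which allows a share of up to 8.97% (95% Wilson interval).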
